A study of Mus musculus with 24 samples.

How the data were processed

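Total RNA from whole lung was made into biotin-labelled cRNA with an Ambion MessageAmp kit, per the labels' protocols, and read on Illumina beadchips. The route and dose of LPS and the number of animals behind a sample are not given in the sources used here, so p-values measure only the spread between these samples, which may be technical. The deposited scanner table holds, per the file headers, an average bead signal, a linear intensity, for 24046 probes on 24 arrays, and for each a detection score, a fraction that is 1 for a probe brighter than all negative controls. The authors' value table holds 13029 of these probes on a log2 scale; set against the scanner signals, each column equalled log2 of 1 array minus that array's mean over the listed probes, within 0.005, with column medians of -0.546 to -0.371. How those probes were chosen is not given in the sources used here.

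Each array was tied to its sample through that identity, because the line of sample titles above the scanner columns named another sample for 22 of the 24 arrays and the same one for 2. A value column differed from its own array by at most 0.00054 and from any other by 1.42 or more at some probe. This match rests on values, not on the title line. Checked on the genotypes, Cd3e, Cd3d, Cd79b and Fcmr were each higher in all 12 wild type arrays than in every Rag-1 null array under this assignment, and in 2 or 3 of 12 under the title line. Each of the 3 slides held 8 arrays, 1 of every group, and a group had the same position on every slide, so position and group cannot be told apart. The 3 arrays of a group were its replicates, numbered as in the labels. Replicate number and slide mark the same arrays, so the slide as a block and the number as a block are 1 fit.

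Signals were corrected for background from the detection scores, quantile normalized and put on the log2 scale (neqc, offset 16, limma 3.58.1 in R 4.3.3). Quantile normalization gives the brightest probes of every array nearly the same value, which limits changes such as those of Saa3 and Sftpc. Probes with a detection p, 1 minus the score, under 0.05 in at least 3 arrays were tested, 13544 in all; 12942 of them were in the value table. Detected probes per array numbered 9517 to 12125 and the median signal was 31.0 to 47.9. The platform annotation gave 1 symbol to 11734 value-table probes and several to 0, and left 1295 unlisted; 11724 matched the reference by Entrez ID, 10 did not, and 0 symbols changed. The symbol of 1 ribosomal RNA probe was set aside after it was seen to be another gene's. Of the tested probes 11658 had a symbol, for 9605 genes, and 1886 had none and were counted but not named. The value of a gene is that of its brightest probe. Of the 1655 genes with 2 or more probes, those with 2 called probes disagreed in direction in 23 of 392 genes in wild type lung at day 1 and 10 of 189 at day 4, and in Rag-1 null lung in 3 of 140 and 7 of 249. Between genotypes they disagreed in 9 of 229 genes at day 1 and 1 of 87 in the mean of 4 times, and from day 4 to day 10 in 2 of 108 and 1 of 68; in the other comparisons in 0.

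One limma model of 8 group means over all 24 arrays gave 17 contrasts and an F statistic over the 3 contrasts of the LPS response between genotypes (eBayes with an intensity trend, two-sided, Benjamini-Hochberg over the probes tested, adjusted p under 0.05). The groups, the model, its alternatives, 25 gene lists and the rule for named genes were fixed before the data were examined. That rule took the 8 largest rises and 8 largest falls past the threshold, 1 probe per gene and skipping clone, RIKEN, LOC, Gm and accession names, up to 4 members with the smallest adjusted p of each list that passed, 17 anchor genes, of which 13 had a tested probe and 1 is not reported here, and every gene where 5 or fewer probes passed. Lists were tested with camera (preset correlation 0.01, adjusted over the 25 lists of a comparison), again with an estimated correlation, and with fry, on 1 probe per gene; list medians use fitted values, members below background included. Measured members, with those also in another list in parentheses, were acute phase 27 (1), adipose 3 (0), airway 18 (0), alternative activation 13 (1), alveolar type 1 12 (0), alveolar type 2 18 (1), B cell 14 (1), cardiac 8 (0), proliferation 28 (0), endothelial 22 (0), erythroid 4 (0), matrix 26 (2), immediate early 10 (0), cytokine 28 (1), interferon gamma 18 (0), MHC class II 15 (0), macrophage 18 (0), neutrophil 17 (0), NK 14 (0), oxidative stress 17 (0), regulatory T cell 7 (0), skeletal muscle 7 (0), T cell 14 (1), thymocyte 7 (2) and type I interferon 18 (0).

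Alternatives were no background correction, cyclic loess, the value table, no detection filter, a stricter one (0.01 in at least 6 arrays), only the compared arrays, array weights (gene-by-gene method, since REML did not converge; 0.0990 to 3.21), no trend, a robust prior, 1 probe per gene, slide as a fixed or random block (statmod 1.5.0) and leaving out each array. Chosen after seeing the data were leaving out 2 wild type arrays (control replicate 1 and LPS day 1 replicate 1) and background correction with centring only. Tested on simulated data of 13544 probes, the model recovered 34.3%, 80.6% and 98.5% of log2 changes of 0.5, 1 and 2 in wild type lung at day 4, and 11.9%, 50.7% and 89.4% in the day 10 difference of responses. It recovered 85.1%, 98.5% and 100% in the mean of 4 times and 4.48%, 58.2% and 97.0% by the F statistic; a simulated list shift was called, with 0 of the other lists.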

Results

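Whole lungs of male C57BL/6 mice were profiled on beadchip arrays that hold 24046 probes. The design crossed 2 genotypes, wild type and Rag-1 null, with 4 conditions, control lung and lung taken 1, 4 or 10 days after lipopolysaccharide (LPS), the endotoxin of Gram-negative bacteria. Rag-1 is needed to assemble antigen receptor genes, so mice without it lack mature T and B cells. The title of the series names the resolution of lung injury by regulatory T cells, and the genotypes and days set the comparisons. Each of the 8 groups held 3 arrays, 24 in all, spread over 3 slides with 1 array of every group on each slide. Between 9517 and 12125 probes per array lay above background, and 13544 probes were tested, of which 11658 named 9605 genes. The number of arrays limits the precision. Replicate arrays correlated at 0.966 to 0.992 in 7 groups and at 0.858 to 0.969 across probes in wild type lung at day 1. Values after gene names are log2 fold changes ± the standard error from limma, with 3 arrays in each group, and a gene or probe passed at an adjusted p under 0.05. Where a probe was not above background on any array of a group, the fold is written as at least N: the mean of the brighter group against, on each array of the dimmer group, the higher of the lowest signal among detected probes and the probe's own. Every gene named here moved in 1 direction on all 3 slides, except 5 that are given with their values on each slide.

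The Rag1 probe lay near background in both genotypes, at 4.28 to 4.76 on the log2 scale in wild type arrays and 4.45 to 4.94 in Rag-1 null arrays, so it checked nothing about the labels. Mean levels of Rag1 in wild type lung were 4.49 ± 0.17 (SD) in control, 4.46 ± 0.16 at day 1, 4.49 ± 0.07 at day 4 and 4.59 ± 0.18 at day 10. In Rag-1 null lung they were 4.59 ± 0.15, 4.61 ± 0.10, 4.62 ± 0.27 and 4.55 ± 0.07. Lymphocyte genes separated the genotypes: Cd3e and Cd3d of the T cell receptor complex, Cd79b of the B cell receptor and Fcmr, the Fc receptor for IgM, were each higher in all 12 wild type arrays than in every Rag-1 null array. Probes for Foxp3, Cd4 and Cd8a were not tested.

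**Figure D1:**
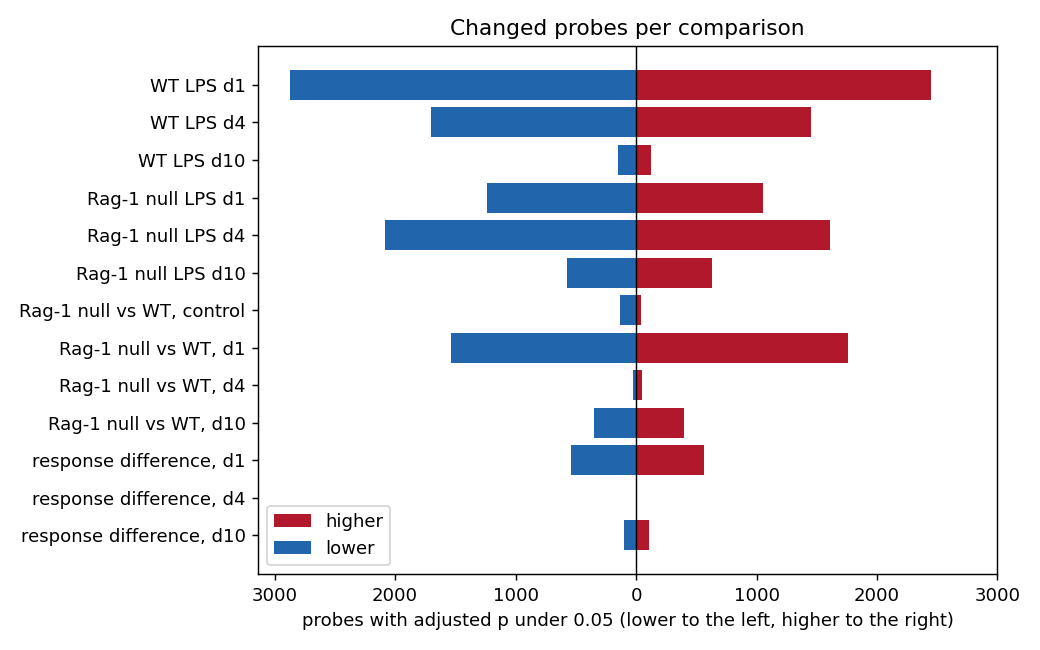
Probes with an adjusted p under 0.05 in 13 comparisons, lower ones to the left and higher ones to the right of 0, on an axis that counts probes. Wild type lung had 5316 changed probes at day 1 and 278 at day 10, and Rag-1 null lung 2287 and 1202. The order of the genotypes at day 1 was reversed where only the compared arrays were fitted.

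In wild type lung 1 day after LPS, acute phase, interferon and chemokine genes rose together while genes of endothelium and of alveolar and airway epithelium fell. Saa3, a serum amyloid A, rose 146-fold (7.19 ± 0.39), and Rsad2, an interferon-induced antiviral protein, rose 86.0-fold (6.43 ± 0.41). The neutrophil-attracting chemokine genes Cxcl1 and Cxcl2 rose by 5.48 ± 0.53 and at least 41.9-fold, Cxcl10 at least 40.0-fold, and Ccl3 at least 17.4-fold. Mt2, a metallothionein that binds metal ions, rose by 5.72 ± 0.35, and Ccl4 by 4.76 ± 0.51. Among the genes that fell were Cavin2, a caveolar coat protein (-2.92 ± 0.20), Nrp1, a co-receptor for vascular endothelial growth factor (-2.73 ± 0.22), Clec1a (-2.76 ± 0.20) and Limch1 (-3.14 ± 0.20). In all, 5316 probes passed, 2445 higher and 2871 lower.

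Of the acute phase and NF-kB response list, 24 of 27 rose and 3 did not pass (25 rose adjusted over the list alone, list adjusted p = 4.54e-16, adjusted p = 0.0532 with an estimated correlation). Lcn2 rose by 4.42 ± 0.29 and the NF-kB inhibitor Tnfaip3 by 3.61 ± 0.26. In the type I interferon response list, 15 of 18 rose and 3 did not pass (15 rose adjusted over the list alone, list adjusted p = 4.00e-11, adjusted p = 0.118 with an estimated correlation). Mx2 rose at least 12.4-fold and Ifit2 by 4.36 ± 0.30. For inflammatory cytokines and chemokines, 21 of 28 rose, 2 fell and 5 did not pass (22 rose and 3 fell adjusted over the list alone, list adjusted p = 1.87e-09, adjusted p = 0.0917 with an estimated correlation). Il6 rose at least 8.01-fold, Tnf at least 2.51-fold, Ccl2 at least 10.1-fold and Il1b by 3.50 ± 0.56. For the interferon gamma response, 14 of 18 rose and 4 did not pass (15 rose adjusted over the list alone, list adjusted p = 4.54e-07, adjusted p = 0.267 with an estimated correlation). Of neutrophil genes, 14 of 17 rose and 3 did not pass (15 rose adjusted over the list alone, list adjusted p = 8.23e-07, adjusted p = 0.263 with an estimated correlation). Of the oxidative stress and metallothionein genes, 12 of 17 rose, 2 fell and 3 did not pass (12 rose and 2 fell adjusted over the list alone, list adjusted p = 1.49e-05, adjusted p = 0.0695 with an estimated correlation). In the endothelial list 1 of 22 rose, 16 fell and 5 did not pass (1 rose and 17 fell adjusted over the list alone, list adjusted p = 1.64e-04, adjusted p = 0.0695 with an estimated correlation). Tek, the angiopoietin receptor, changed by -2.37 ± 0.30 and the transcription factor Sox17 by -1.57 ± 0.21. Of the alveolar type 2 list, 12 of 18 fell and 6 did not pass (13 fell adjusted over the list alone, list adjusted p = 1.64e-04, adjusted p = 0.209 with an estimated correlation). Etv5 (-2.38 ± 0.18), Nkx2-1, the lung epithelial transcription factor (-2.04 ± 0.21), and Abca3, which moves surfactant lipid (-1.26 ± 0.17), fell. Airway epithelial genes included Cyp2f2, a cytochrome P450 of club cells (-2.03 ± 0.31), and Tppp3 (-1.94 ± 0.17). Of that list 12 of 18 fell and 6 did not pass (12 fell adjusted over the list alone, list adjusted p = 3.90e-04, adjusted p = 0.340 with an estimated correlation).

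Of the alveolar type 1 list, 7 of 12 fell and 5 did not pass (9 fell adjusted over the list alone, list adjusted p = 9.21e-04, adjusted p = 0.169 with an estimated correlation). Among MHC class II presentation genes, 2 of 15 rose, 9 fell and 4 did not pass (2 rose and 10 fell adjusted over the list alone, list adjusted p = 0.0180, adjusted p = 0.405 with an estimated correlation). Of the B and plasma cell list, 10 of 14 fell and 4 did not pass (10 fell adjusted over the list alone, list adjusted p = 5.22e-04, adjusted p = 0.267 with an estimated correlation). Of the regulatory T cell list, 6 of 7 rose and 1 fell (6 rose and 1 fell adjusted over the list alone, list adjusted p = 0.00337, adjusted p = 0.0695 with an estimated correlation). The genes Tnfrsf9, which rose at least 2.51-fold, Ebi3 at least 5.64-fold and Il10 at least 1.29-fold, are also made by other activated immune cells. Beside these groups, of erythroid genes, markers of red blood cells, 3 of 4 rose and 1 did not pass (4 rose adjusted over the list alone, list adjusted p = 0.0388, adjusted p = 0.405 with an estimated correlation). Above background on part of 1 group's arrays lay Abca3 (2 of 3) and Etv5 (1 of 3). With slide as a block 5411 probes passed. Of the changed probes 93.8% moved 1 way on all 3 slides, which selection by p favours in every comparison. Fitted on the 6 compared arrays alone, 2117 passed.

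At day 4 acute phase, macrophage and cell division genes were above control in wild type lung. Saa3 was 199-fold above control (7.64 ± 0.39), complement factor Cfb rose by 4.08 ± 0.32, the interferon-induced chemokine Cxcl9 at least 30.2-fold and the arginase Arg1 at least 10.6-fold. Retnla, a resistin-like protein of alternatively activated macrophages, rose by 3.64 ± 0.49, Cxcl13, a B cell attractant, by 3.63 ± 0.50, and Timp1, an inhibitor of matrix metalloproteinases, by 3.62 ± 0.43. The paraoxonase Pon1 (-3.34 ± 0.30), complement C5, encoded by Hc (-2.35 ± 0.32), the endothelin receptor Ednrb (-2.34 ± 0.27) and Cyp2f2 (-2.13 ± 0.31) fell. A total of 3152 probes passed, 1450 higher and 1702 lower (46.0% higher, or 35.9% where arrays were only centred).

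Of the cell proliferation genes, 26 of 28 rose and 2 did not pass (27 rose adjusted over the list alone, list adjusted p = 6.07e-18, adjusted p = 0.117 with an estimated correlation). The proliferation marker Mki67 rose by 1.24 ± 0.23, Top2a at least 2.60-fold and Cdk1 at least 2.86-fold. For monocytes and macrophages, 16 of 18 rose, 1 fell and 1 did not pass (16 rose and 1 fell adjusted over the list alone, list adjusted p = 1.34e-16, adjusted p = 1.24e-05 with an estimated correlation). Adgre1, a macrophage surface receptor, rose by 2.60 ± 0.19, the cathepsin K gene Ctsk by 2.67 ± 0.20 and complement C1qb by 3.17 ± 0.25. Acute phase genes rose, with 13 of 27 up and 14 not passing (15 up adjusted over the list alone, list adjusted p = 2.59e-11, adjusted p = 0.0713 with an estimated correlation). Interferon gamma response genes did too, with 14 of 18 up and 4 not passing (17 up adjusted over the list alone, list adjusted p = 9.86e-11, adjusted p = 0.195 with an estimated correlation). Of the extracellular matrix list, 13 of 26 rose, 1 fell and 12 did not pass (13 rose and 1 fell adjusted over the list alone, list adjusted p = 2.83e-06, adjusted p = 0.127 with an estimated correlation). Tgfbi rose by 2.93 ± 0.16, Mmp14 by 2.06 ± 0.21 and Col1a1 by 1.54 ± 0.26. In the neutrophil list 9 of 17 rose and 8 did not pass (9 rose adjusted over the list alone, list adjusted p = 2.83e-06, adjusted p = 0.250 with an estimated correlation). Its medians on the 3 slides were 2.72, -0.46 and 1.04. Endothelial genes fell, with 11 of 22 down and 11 not passing (12 down adjusted over the list alone, list adjusted p = 9.77e-06, adjusted p = 0.0599 with an estimated correlation). B and plasma cell genes also fell, with 10 of 14 down and 4 not passing (3 up and 10 down adjusted over the list alone, list adjusted p = 0.0115, adjusted p = 0.331 with an estimated correlation). The arrays above background in 1 group were fewer than 3 for Cxcl13 (1 of 3). With slide as a block 3247 probes passed, and 98.4% of the changed probes moved 1 way on every slide. Without replicate 1 of wild type LPS day 4 the count was 1869, and 5166 with the deposited values.

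At day 10, 278 probes differed from control in wild type lung (128 higher, 150 lower), with matrix and macrophage genes above control. Among the rises were Eln, elastin (2.33 ± 0.50), Col1a2 (1.70 ± 0.32) and Col3a1 (1.68 ± 0.39), with Spon2 (1.91 ± 0.37), Slc26a4, the anion exchanger pendrin (1.81 ± 0.24), and Saa3 (1.68 ± 0.39). Dbp (-3.47 ± 0.52) and Tef (-1.57 ± 0.37), which act downstream of the circadian clock, and the clock repressors Per2 (-1.94 ± 0.26) and Nr1d1 (-1.64 ± 0.28) fell, and Arntl, a clock activator, rose (1.68 ± 0.29). These genes were set together after their values were seen. The B cell gene Fcrl1 (-1.28 ± 0.14) and the galanin gene Gal, at least 2.01-fold, also fell. Of the extracellular matrix list, 7 of 26 rose, 1 fell and 18 did not pass (15 rose and 2 fell adjusted over the list alone, list adjusted p = 8.03e-08, adjusted p = 0.0937 with an estimated correlation). Of alveolar type 2 genes 2 of 18 rose and 16 did not pass (7 rose adjusted over the list alone, list adjusted p = 8.03e-08, adjusted p = 0.0937 with an estimated correlation). Abca3 rose by 0.76 ± 0.17. Of macrophage genes, 4 of 18 rose and 14 did not pass (8 rose adjusted over the list alone, list adjusted p = 1.12e-07, adjusted p = 0.00164 with an estimated correlation). Ctsk rose by 1.29 ± 0.20, Itgax by 1.21 ± 0.21 and the elastase Mmp12 by 1.01 ± 0.20. For MHC class II genes 4 of 15 rose and 11 did not pass (8 rose adjusted over the list alone, list adjusted p = 2.76e-05, adjusted p = 0.143 with an estimated correlation). H2-Aa rose by 1.06 ± 0.22. For alternative macrophage activation 2 of 13 rose and 11 did not pass (5 rose and 1 fell adjusted over the list alone, list adjusted p = 7.65e-04, adjusted p = 0.0937 with an estimated correlation). Chil3 rose by 1.49 ± 0.36. B and plasma cell genes were lower, with 4 of 14 down and 10 not passing (7 down adjusted over the list alone, list adjusted p = 3.45e-06, adjusted p = 0.143 with an estimated correlation). T cell genes were lower too, with 2 of 14 down and 12 not passing (6 down adjusted over the list alone, list adjusted p = 7.91e-06, adjusted p = 0.143 with an estimated correlation), as was the neutrophil list, with 0 of 17 past the threshold (0 adjusted over the list alone, list adjusted p = 0.0180, adjusted p = 0.592 with an estimated correlation), and medians of 0.18, -1.37 and -0.29 on the 3 slides. Heart muscle genes lay higher beside these groups, with 0 of 8 past the threshold (1 up adjusted over the list alone, list adjusted p = 0.00120, adjusted p = 0.445 with an estimated correlation). The list's medians were -0.38, 2.24 and 1.75 on the 3 slides. Skeletal muscle genes lay higher too, with 0 of 7 past the threshold (1 up adjusted over the list alone, list adjusted p = 0.0123, adjusted p = 0.445 with an estimated correlation). Above background on only some arrays of 1 group were Arntl (2 of 3), Fcrl1 (2 of 3), Mmp12 (1 of 3) and Slc26a4 (2 of 3). With slide as a block 366 probes passed, and 46.0% of calls were higher, against 25.6% with the deposited value table (1337 called) and 29.4% where arrays were only centred (497 called). Leaving out 1 array gave 62 (wild type LPS day 10 replicate 1), 125 (replicate 2) or 76 (replicate 3), and 663 or 504 without wild type LPS day 1 replicate 1 or 2. A stricter detection filter gave 132 and array weights 986.

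In Rag-1 null lung at day 1, acute phase and chemokine genes rose and airway and alveolar genes fell, among 2287 probes that differed from its own control (1050 higher, 1237 lower). Saa3 rose 316-fold (8.30 ± 0.39), with all 3 LPS arrays at the highest normalized value, which limits the fold that can be measured. Ccl3 rose by 5.91 ± 0.48, Cxcl1 by 5.17 ± 0.53, Cxcl2 at least 44.6-fold, Timp1 by 5.27 ± 0.43, Il4i1, an amino acid oxidase, by 5.25 ± 0.36 and Orm1, an acute phase plasma protein, by 4.95 ± 0.38. Dbp (-3.30 ± 0.52), Hc (-3.04 ± 0.32), Cyp2f2 (-2.55 ± 0.31) and the integrin Itga8 (-2.45 ± 0.31) fell. Acute phase genes rose as a group, with 25 of 27 up and 2 not passing (26 up adjusted over the list alone, list adjusted p = 1.11e-31, adjusted p = 0.00237 with an estimated correlation). So did cytokine and chemokine genes, with 19 of 28 up, 2 down and 7 not passing (19 up and 2 down adjusted over the list alone, list adjusted p = 6.65e-16, adjusted p = 0.0336 with an estimated correlation). In the monocyte and macrophage list 8 of 18 rose, 1 fell and 9 did not pass (10 rose and 2 fell adjusted over the list alone, list adjusted p = 0.00101, adjusted p = 0.0336 with an estimated correlation). The LPS co-receptor Cd14 rose by 3.78 ± 0.35. Neutrophil genes rose too, with 12 of 17 up and 5 not passing (14 up adjusted over the list alone, list adjusted p = 3.98e-12, adjusted p = 0.129 with an estimated correlation). Clec4d rose by 3.89 ± 0.29 and the granule protein gene S100a8 by 3.26 ± 0.70. Of type I interferon genes 8 of 18 rose and 10 did not pass (11 rose adjusted over the list alone, list adjusted p = 2.30e-07, adjusted p = 0.194 with an estimated correlation). Of interferon gamma genes 9 of 18 rose and 9 did not pass (13 rose adjusted over the list alone, list adjusted p = 2.30e-07, adjusted p = 0.260 with an estimated correlation). Airway genes fell, with 9 of 18 down and 9 not passing (13 down adjusted over the list alone, list adjusted p = 1.92e-08, adjusted p = 0.132 with an estimated correlation). Alveolar type 2 genes fell too, with 1 of 18 up, 11 down and 6 not passing (1 up and 11 down adjusted over the list alone, list adjusted p = 3.46e-05, adjusted p = 0.147 with an estimated correlation). The surfactant protein gene Sftpc changed by -1.43 ± 0.21, with all 3 control arrays at the highest normalized value. Heart muscle genes fell beside the airway list, with 5 of 8 down and 3 not passing (6 down adjusted over the list alone, list adjusted p = 0.00463, adjusted p = 0.391 with an estimated correlation). Above background on part of 1 group's arrays lay Ccl3 (1 of 3). With slide as a block 2373 probes passed, and 99.6% of the changed probes moved 1 way on every slide. The count was 1468 without Rag-1 null LPS day 1 replicate 2, 4319 with only the compared arrays and 4906 with array weights.

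At day 4 interferon gamma, acute phase and macrophage genes rose in Rag-1 null lung and endothelial and alveolar genes fell. Cxcl9 rose 88.8-fold (6.47 ± 0.42), Ubd, a ubiquitin-like modifier, at least 13.1-fold, Ifng itself at least 3.22-fold, and Cxcl10 at least 23.6-fold. Saa3 (8.21 ± 0.39, 2 of 3 LPS arrays at the highest normalized value), Ccl3 (4.54 ± 0.48), Timp1 (4.51 ± 0.43), Clec4d (4.47 ± 0.29) and Orm1 (4.32 ± 0.38) rose, and Clec4e, a receptor for mycobacterial glycolipid, rose at least 19.4-fold. Hc (-3.34 ± 0.32), Pon1 (-3.21 ± 0.30), Cyp2f2 (-2.79 ± 0.31), Dbp (-3.34 ± 0.52) and the cardiac actin gene Actc1 (-2.82 ± 0.72) fell, among 3686 changed probes (1606 higher, 2080 lower). Of the interferon gamma list 18 of 18 rose (18 rose adjusted over the list alone, list adjusted p = 2.64e-18, adjusted p = 0.0648 with an estimated correlation). Of type I interferon genes 15 of 18 rose and 3 did not pass (16 rose adjusted over the list alone, list adjusted p = 1.05e-10, adjusted p = 0.106 with an estimated correlation), and of acute phase genes 21 of 27 rose and 6 did not pass (23 rose adjusted over the list alone, list adjusted p = 1.14e-14, adjusted p = 0.0271 with an estimated correlation). Macrophage genes rose, with 14 of 18 up, 1 down and 3 not passing (15 up and 1 down adjusted over the list alone, list adjusted p = 2.90e-12, adjusted p = 9.75e-05 with an estimated correlation). Adgre1 rose by 2.54 ± 0.19 and C1qb by 3.20 ± 0.25. Neutrophil genes rose too, with 16 of 17 up and 1 not passing (16 up adjusted over the list alone, list adjusted p = 4.89e-12, adjusted p = 0.0966 with an estimated correlation). Of endothelial genes 19 of 22 fell and 3 did not pass (19 fell adjusted over the list alone, list adjusted p = 5.93e-10, adjusted p = 0.00445 with an estimated correlation). Tmem100 (-2.21 ± 0.22), Ednrb (-2.44 ± 0.27) and the vascular phosphatase Ptprb (-2.06 ± 0.22) fell. Alveolar type 2 genes fell, with 13 of 18 down and 5 not passing (15 down adjusted over the list alone, list adjusted p = 8.35e-06, adjusted p = 0.106 with an estimated correlation). Cell proliferation genes rose, with 18 of 28 up, 1 down and 9 not passing (20 up and 1 down adjusted over the list alone, list adjusted p = 2.91e-07, adjusted p = 0.271 with an estimated correlation). Of NK and cytotoxic cell genes 4 of 14 rose, 1 fell and 9 did not pass (5 rose and 1 fell adjusted over the list alone, list adjusted p = 0.00666, adjusted p = 0.359 with an estimated correlation). The list's medians were -0.08, 0.41 and 0.67 on the 3 slides. The chemokines Xcl1 (3.19 ± 0.35) and Ccl5 (2.84 ± 0.32) rose. Heart muscle genes fell beside them, with 5 of 8 down and 3 not passing (5 down adjusted over the list alone, list adjusted p = 0.0285, adjusted p = 0.472 with an estimated correlation). The arrays above background in 1 group were fewer than 3 for Ccl3 (1 of 3). With slide as a block 3755 probes passed, and 99.4% of the changed probes moved 1 way on every slide. Array weights gave 5920.

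At day 10 Rag-1 null lung differed from its control at 1202 probes (628 higher, 574 lower). Saa3 was 40.2-fold above control (5.33 ± 0.39). Above control too were Gpnmb, a glycoprotein of lipid-laden macrophages (3.68 ± 0.42), Cxcl9 (3.64 ± 0.42), Clec4d (3.26 ± 0.29), Trem2, a lipid-sensing macrophage receptor (2.89 ± 0.29), Ctsk (2.86 ± 0.20), Slc26a4 (3.58 ± 0.24) and Cfb (2.76 ± 0.32). Among those that fell were Ednrb (-2.56 ± 0.27), Tmem100 (-1.98 ± 0.22), Plvap, a component of endothelial diaphragms (-1.93 ± 0.25), and Smad6, an inhibitor of BMP signalling (-1.93 ± 0.29), with Dbp (-2.65 ± 0.52) and Cyp4b1 (-1.97 ± 0.30). Macrophage genes rose, with 13 of 18 up and 5 not passing (13 up and 1 down adjusted over the list alone, list adjusted p = 1.08e-18, adjusted p = 5.52e-06 with an estimated correlation). Mmp12 rose by 2.64 ± 0.20. Endothelial genes fell, with 13 of 22 down and 9 not passing (16 down adjusted over the list alone, list adjusted p = 4.24e-13, adjusted p = 8.68e-04 with an estimated correlation). Cell proliferation genes rose, with 21 of 28 up and 7 not passing (25 up adjusted over the list alone, list adjusted p = 1.21e-22, adjusted p = 0.0583 with an estimated correlation). Mki67 rose by 1.63 ± 0.23 and the mitotic kinase gene Plk1 by 1.57 ± 0.24. MHC class II genes rose, with 10 of 15 up and 5 not passing (11 up adjusted over the list alone, list adjusted p = 9.34e-10, adjusted p = 0.0378 with an estimated correlation). Alternative activation genes rose, with 6 of 13 up and 7 not passing (8 up adjusted over the list alone, list adjusted p = 1.61e-06, adjusted p = 0.0163 with an estimated correlation). Arg1 rose at least 3.91-fold. The type I interferon list was not called (list adjusted p = 0.443). Above background on only some arrays of 1 group were Trem2 (1 of 3). With slide as a block 1239 probes passed, and 99.4% of the changed probes moved 1 way on every slide. The count was 783 without Rag-1 null LPS day 10 replicate 2, 1983 with the compared arrays alone and 3417 with array weights. It was 1854 without the 2 wild type arrays, chosen after seeing the data, whose heart and airway genes lay highest in their group. Arrays of other groups stood out too and were left out only in turn, such as Rag-1 null LPS day 10 replicate 2.

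**Figure D2:**
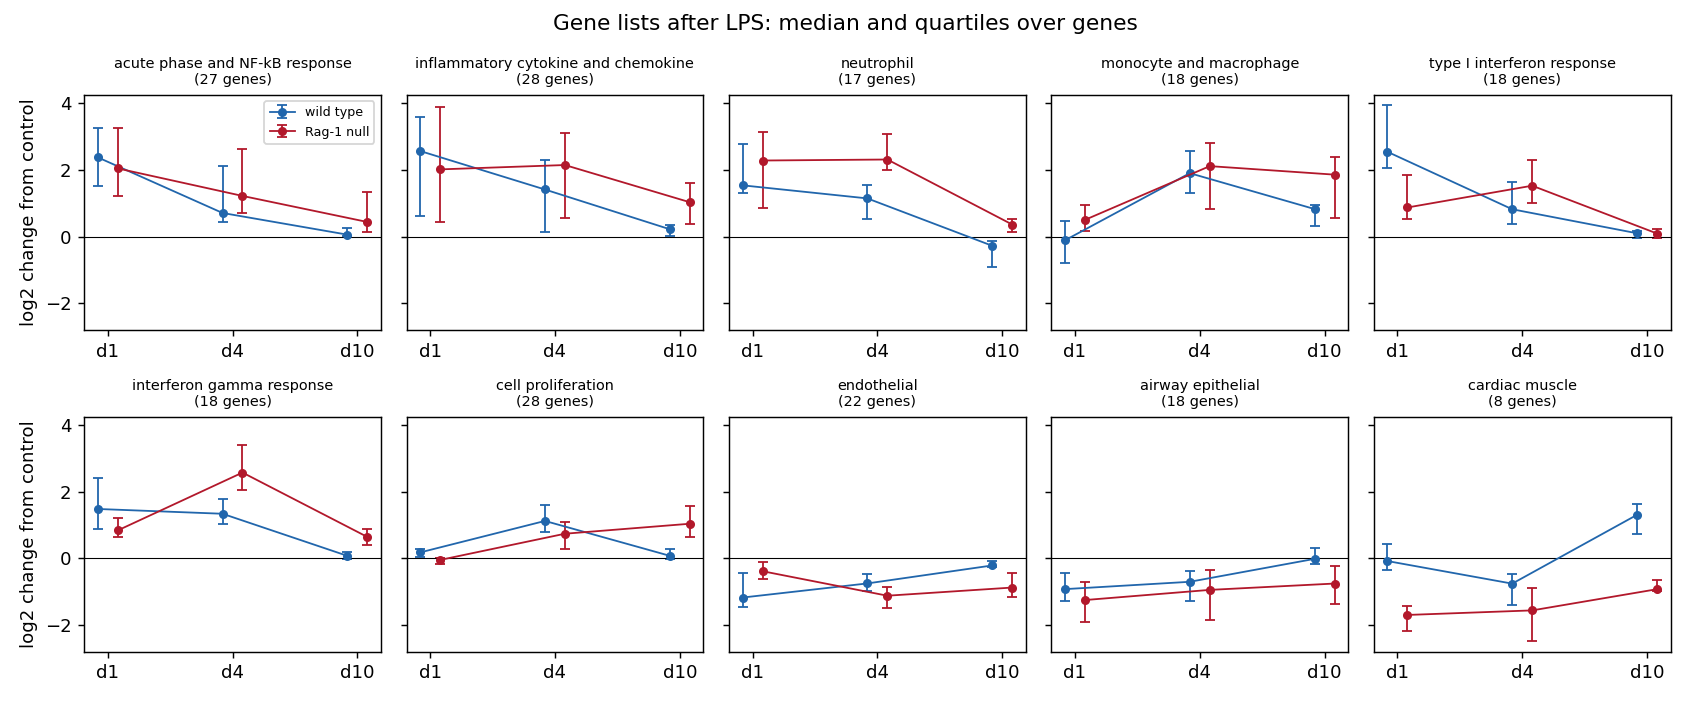
Median log2 change from control of the measured genes of 10 lists at days 1, 4 and 10 (d1, d4, d10), with bars from the first to the third quartile over genes, for wild type and Rag-1 null lung. The median of the monocyte and macrophage list at day 10 was 0.83 in wild type and 1.86 in Rag-1 null lung.

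Across probes, the changes in both genotypes correlated at 0.722 at day 1, 0.844 at day 4 and 0.311 at day 10. Probes are not independent replicates. At day 4, 970 probes rose and 1085 fell in both genotypes, against 172 and 261 for independent lists, and 6 moved in opposite directions. At day 1 the shared numbers were 760 up (190 for independent lists), 924 down (262) and 29 opposite. At day 10 they were 46 up (5.94), 33 down (6.36) and 5 opposite.

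In control lung, lymphocyte genes were lower in Rag-1 null than in wild type mice. Fcmr was at least 10.0-fold lower in Rag-1 null lung, Ly6d at least 5.51-fold and Cd3e at least 3.21-fold. Cd8b1 (-2.62 ± 0.26), Cd79b (-2.32 ± 0.23), Cd3d (-2.21 ± 0.20) and the lymph node homing receptor Ccr7 (-1.78 ± 0.30) were lower too. The immunoglobulin light chain segment Igkv6-15 was at least 3.05-fold lower. Among the higher genes were Tuba1a at 1.27 ± 0.31, the peptidase Enpep at 0.97 ± 0.20 and Ccl17 at 0.85 ± 0.18. Of B and plasma cell genes 9 of 14 were lower and 5 did not pass (11 lower adjusted over the list alone, list adjusted p = 2.31e-26, adjusted p = 0.00171 with an estimated correlation). Of T cell genes 10 of 14 were lower and 4 did not pass (13 lower adjusted over the list alone, list adjusted p = 2.77e-25, adjusted p = 0.00171 with an estimated correlation). The thymocyte list was also lower, with 2 of 7 lower and 5 not passing (3 lower adjusted over the list alone, list adjusted p = 6.43e-04, adjusted p = 0.0501 with an estimated correlation). The lower members were Cd8b1 and Ly6d, which the T cell and B cell lists also hold. Heart muscle genes lay higher in Rag-1 null lung, with 0 of 8 past the threshold (1 higher adjusted over the list alone, list adjusted p = 0.00462, adjusted p = 0.648 with an estimated correlation). Its medians on the 3 slides were -0.35, 0.51 and 2.59. Neutrophil genes lay lower, with 0 of 17 past the threshold (0 adjusted over the list alone, list adjusted p = 0.00490, adjusted p = 0.733 with an estimated correlation), and medians of 0.06, -1.13 and -0.23 on the 3 slides. The alveolar type 2, alternative activation, proliferation, matrix, skeletal muscle and NK lists lay higher, with medians of 0.30, 0.31, 0.15, 0.18, 0.29 and 0.28, list adjusted p = 0.00387 to 0.00985, adjusted p = 0.197 to 0.854 with an estimated correlation, and 1 member in all past the threshold, Ccl17. Above background on part of 1 group's arrays lay Cd3d (1 of 3) and Cd8b1 (1 of 3). In all 174 probes passed, 39 higher and 135 lower, and 190 with slide as a block (99.4% of calls in 1 direction on every slide). Leaving out Rag-1 null control replicate 1, 2 or 3 gave 78, 81 or 58, and leaving out wild type LPS day 1 replicate 1 or 2 gave 350 or 314. The value table gave 940, array weights 486, the compared arrays alone 93 and a stricter filter 84.

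One day after LPS, type I interferon genes were lower in Rag-1 null than in wild type lung. Mx2, an interferon-induced GTPase, differed by -3.22 ± 0.23 (wild type 8.37 ± 0.57, Rag-1 null 5.15 ± 0.31, SD), Rsad2 by -3.78 ± 0.41, the nucleotide kinase Cmpk2 by -2.91 ± 0.24 and Oasl1 by -2.92 ± 0.35. Dio2, the deiodinase that activates thyroid hormone (-3.62 ± 0.17), Hamp, which encodes the iron regulator hepcidin (-3.52 ± 0.50), and the cytokine gene Il24 (at least 8.17-fold) were lower as well. Higher in Rag-1 null lung were Xcl1, a chemokine of NK and T cells (2.62 ± 0.35), Akr1c14 (2.72 ± 0.31), Saa1 (2.55 ± 0.42), Clec1a (2.30 ± 0.20), Clec4n (2.24 ± 0.22) and Arg1 (2.11 ± 0.49). Of the type I interferon list 13 of 18 were lower and 5 did not pass (14 lower adjusted over the list alone, list adjusted p = 1.09e-08, adjusted p = 0.341 with an estimated correlation). T cell genes were lower, with 7 of 14 lower and 7 not passing (1 higher and 9 lower adjusted over the list alone, list adjusted p = 4.73e-04, adjusted p = 0.341 with an estimated correlation). The interleukin 7 receptor gene Il7r differed by -1.83 ± 0.19. Endothelial genes were higher, with 10 of 22 higher, 1 lower and 11 not passing (11 higher and 1 lower adjusted over the list alone, list adjusted p = 0.00310, adjusted p = 0.323 with an estimated correlation). Of alveolar type 2 genes 10 of 18 were higher, 1 lower and 7 did not pass (the same adjusted over the list alone, list adjusted p = 0.00310, adjusted p = 0.341 with an estimated correlation). Sox17 differed by 1.91 ± 0.21 and Nkx2-1 by 1.52 ± 0.21, but Sftpc was lower. Monocyte and macrophage genes were higher, with 7 of 18 higher and 11 not passing (7 higher and 2 lower adjusted over the list alone, list adjusted p = 0.0117, adjusted p = 0.314 with an estimated correlation). Interferon gamma genes were lower, with 7 of 18 lower and 11 not passing (7 lower adjusted over the list alone, list adjusted p = 0.0127, adjusted p = 0.691 with an estimated correlation). Il6 was lower (-1.55 ± 0.47), and Il10 at least 1.42-fold lower. The arrays above background in 1 group were fewer than 3 for Arg1 (1 of 3) and Xcl1 (1 of 3). A total of 3297 probes passed (1759 higher, 1538 lower), 3406 with slide as a block, and 95.3% of them moved 1 way on every slide. With the 6 compared arrays alone 803 passed.

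At day 4 interferon gamma genes were higher in Rag-1 null than in wild type lung, on 2 of the 3 slides. Ubd was 4.43-fold higher (2.15 ± 0.32), the guanylate-binding protein gene Gbp2 higher by 1.63 ± 0.29, Batf2 by 1.91 ± 0.35, Cxcl9 by 1.87 ± 0.42 and Xcl1 by 1.69 ± 0.35. Nos2, the inducible nitric oxide synthase (1.81 ± 0.37), differed by -0.06, 2.15 and 3.34 on the 3 slides, the GTPase gene Tgtp1 (1.69 ± 0.35) by -0.25, 2.07 and 3.24, Ifng (1.57 ± 0.33) by -0.31, 2.21 and 2.81, and Slc7a11, a cystine transporter subunit (0.96 ± 0.20), by -0.06, 1.34 and 1.58. Cd3d (-2.07 ± 0.20), Cd8b1 (-2.15 ± 0.26), Cd79b (-1.14 ± 0.23), Fcmr (at least 4.02-fold) and Cd3e (at least 2.95-fold) were lower. Of the interferon gamma list 7 of 18 were higher and 11 did not pass (16 higher adjusted over the list alone, list adjusted p = 9.24e-26, adjusted p = 0.0357 with an estimated correlation). Its medians on the 3 slides were -0.14, 1.40 and 2.66. Type I interferon genes were higher too, with 1 of 18 higher and 17 not passing (8 higher adjusted over the list alone, list adjusted p = 2.03e-11, adjusted p = 0.0916 with an estimated correlation), and medians of -0.30, 0.67 and 1.78 on the 3 slides. The 1 was Ifit2 (1.35 ± 0.30, a call that ended with slide as a block). T cell genes were lower, with 7 of 14 lower and 7 not passing (8 lower adjusted over the list alone, list adjusted p = 5.95e-16, adjusted p = 0.0112 with an estimated correlation). The endothelial list was lower too, with 0 of 22 past the threshold (0 adjusted over the list alone, list adjusted p = 2.52e-08, adjusted p = 0.0112 with an estimated correlation). For NK and cytotoxic cell genes 3 of 14 were higher and 11 did not pass (5 higher adjusted over the list alone, list adjusted p = 1.20e-10, adjusted p = 0.0550 with an estimated correlation). Above background on only some arrays of 1 group were Batf2 (2 of 3), Cd3d (2 of 3), Cd8b1 (1 of 3), Ifng (1 of 3) and Nos2 (1 of 3). In all 73 probes passed, 46 higher and 27 lower, 63 with slide as a block, and 86.3% of calls moved 1 way on every slide. Of the calls 63.0% were higher, or 50% after cyclic loess. Leaving out Rag-1 null LPS day 4 replicate 1, 2 or 3 gave 311, 17 or 16, wild type LPS day 4 replicate 1, 2 or 3 gave 256, 27 or 14, and wild type LPS day 1 replicate 1 gave 167. Without wild type LPS day 10 replicates 2 and 3, Rag-1 null control replicates 1 and 2 and Rag-1 null LPS day 1 replicate 1, each in turn, it was 45 to 48. The compared arrays alone gave 15 and array weights 994.

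At day 10 macrophage and cell proliferation genes were higher and endothelial genes lower in Rag-1 null than in wild type lung. Saa3 was 11.9-fold higher (3.58 ± 0.39), Cxcl9 higher by 3.46 ± 0.42 and Retnla 10.3-fold (3.37 ± 0.49). Xcl1 (2.51 ± 0.35), Gpnmb (2.45 ± 0.42), Clec4d (2.35 ± 0.29), Clec4e (2.16 ± 0.35) and Arg1 (2.17 ± 0.49) were higher. Lower were Ednrb (-2.13 ± 0.27), Cyp26b1, which degrades retinoic acid (-2.49 ± 0.57), Fcmr (at least 5.33-fold), Cd8b1 (-1.80 ± 0.26) and 4 light chain segments, of which Igkv4-61 differed by -1.78 ± 0.25. Macrophage genes were higher, with 10 of 18 higher and 8 not passing (13 higher adjusted over the list alone, list adjusted p = 1.63e-14, adjusted p = 3.01e-05 with an estimated correlation). Mmp12 differed by 2.01 ± 0.20, Ctsk by 1.56 ± 0.20 and Trem2 by 1.96 ± 0.29. Cell proliferation genes were higher, with 23 of 28 higher and 5 not passing (27 higher adjusted over the list alone, list adjusted p = 1.32e-31, adjusted p = 0.0260 with an estimated correlation). Mki67 differed by 1.68 ± 0.23, Bub1b by 1.12 ± 0.15 and Nusap1 by 1.52 ± 0.23. Of alternative activation genes 3 of 13 were higher and 10 did not pass (5 higher adjusted over the list alone, list adjusted p = 1.13e-05, adjusted p = 0.0260 with an estimated correlation). Ccl17 differed by 2.07 ± 0.18. Endothelial genes were lower, with 10 of 22 lower and 12 not passing (13 lower adjusted over the list alone, list adjusted p = 2.53e-11, adjusted p = 0.00190 with an estimated correlation). Tmem100 differed by -1.63 ± 0.22 and Robo4 by -0.77 ± 0.15. Heart muscle genes lay lower beside them, with 0 of 8 past the threshold (0 adjusted over the list alone, list adjusted p = 0.00746, adjusted p = 0.390 with an estimated correlation). Above background on part of 1 group's arrays lay Arg1 (1 of 3), Cd8b1 (1 of 3), Clec4e (1 of 3) and Igkv4-61 (1 of 3). In all 748 probes passed (402 higher, 346 lower), 752 with slide as a block, and 99.5% of calls moved 1 way on every slide. Leaving out Rag-1 null LPS day 10 replicate 1 or 2 gave 442 or 403, wild type LPS day 10 replicate 1, 2 or 3 gave 489, 456 or 467, and wild type LPS day 1 replicate 1 gave 1156. The compared arrays alone gave 1526, and array weights 3261.

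Averaged over control and the 3 days, 12 arrays against 12, 1691 probes differed (877 higher, 814 lower in Rag-1 null lung; 1778 with slide as a block, 98.9% of calls in 1 direction on every slide). Xcl1 was 3.68-fold higher (1.88 ± 0.18), with Retnla (1.70 ± 0.25), Cxcl9 (1.57 ± 0.21), Ccl17, a chemokine (1.12 ± 0.09), and Timp1 (1.24 ± 0.22). Tnf was higher by 0.52 ± 0.17, with -0.09, 0.69 and 0.95 on the 3 slides (adjusted p = 0.0432, or 0.0529 with slide as a block). Cd8b1 (-2.05 ± 0.13), Cd3d (-1.89 ± 0.10), Cd3e (-1.46 ± 0.11), Cd79b (-1.45 ± 0.11) and Fcmr (-2.43 ± 0.13) were lower. Of the 12 Rag-1 null arrays only 1 lay above background for Fcmr, 2 for Cd3e and 3 each for Cd3d and Cd8b1, so these are fitted values against a floor. The T cell list was lower, with 11 of 14 lower and 3 not passing (12 lower adjusted over the list alone, list adjusted p = 2.07e-17, adjusted p = 0.00701 with an estimated correlation), as was the B and plasma cell list, with 10 of 14 lower and 4 not passing (11 lower adjusted over the list alone, list adjusted p = 1.79e-13, adjusted p = 0.0246 with an estimated correlation). The macrophage list was higher, with 9 of 18 higher, 1 lower and 8 not passing (11 higher and 1 lower adjusted over the list alone, list adjusted p = 1.05e-07, adjusted p = 0.00160 with an estimated correlation). Without wild type LPS day 1 replicate 1 the count was 2921, and with array weights 3781.

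**Figure D3:**
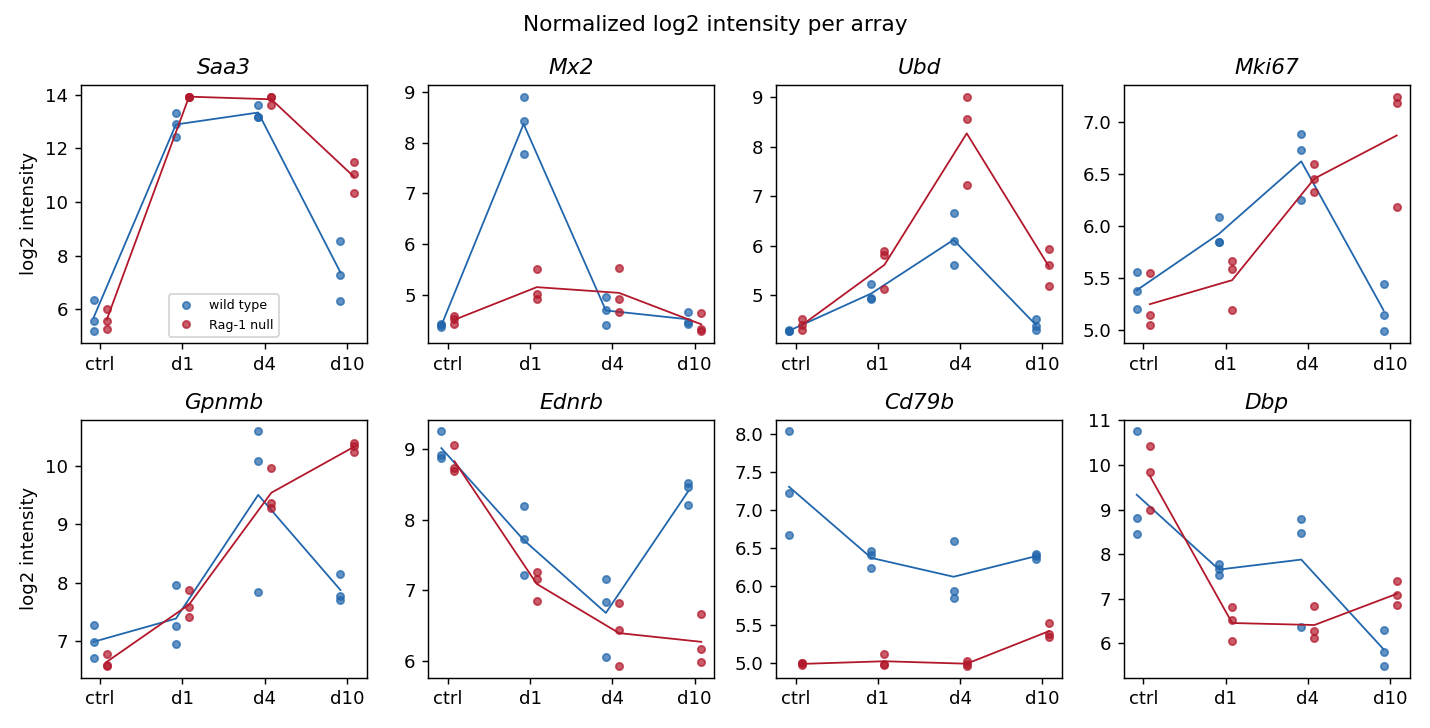
Normalized log2 intensity of 8 genes on each array (points, 3 per group) in control lung (ctrl) and at days 1, 4 and 10 after LPS, with lines through the group means of wild type and Rag-1 null lung. Mx2 at day 1 averaged 8.37 in wild type and 5.15 in Rag-1 null lung, and Saa3 at day 10 averaged 7.38 and 10.95.

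Whether the response to LPS itself differed between genotypes was tested as the Rag-1 null change minus the wild type change, printed as fitted also where a control group lay at background. At day 1, 1112 probes differed (568 higher, 544 lower; 1097 with slide as a block). The Rag-1 null change lay below the wild type change for Hamp (-4.38 ± 0.70), Dio2 (-3.79 ± 0.24), Rsad2 (-3.48 ± 0.58), Mx2 (-3.34 ± 0.33), Il24 (-3.22 ± 0.30) and Gsta2, a glutathione transferase (-3.14 ± 0.34). It lay above it for Clec1a (2.75 ± 0.29), Saa1 (2.50 ± 0.60), Fcer2a (2.45 ± 0.43), Clec4n (2.18 ± 0.31) and Aif1, a macrophage calcium-binding protein (2.05 ± 0.22). Of type I interferon genes 9 of 18 were lower and 9 did not pass (12 lower adjusted over the list alone, list adjusted p = 1.84e-08, adjusted p = 0.291 with an estimated correlation). Of B and plasma cell genes 7 of 14 were higher and 7 did not pass (8 higher adjusted over the list alone, list adjusted p = 8.94e-06, adjusted p = 0.291 with an estimated correlation). Of those 7, 6 lay above background on no Rag-1 null control array, where no fall could be measured. Fcer2a is 1 of them; Saa1 and Il24 lay above background on no control array of either genotype, Dio2 and Mx2 on none of wild type. Endothelial responses were higher, with 4 of 22 higher and 18 not passing (6 higher and 1 lower adjusted over the list alone, list adjusted p = 0.0121, adjusted p = 0.291 with an estimated correlation). Heart muscle genes lay lower, with 0 of 8 past the threshold (0 adjusted over the list alone, list adjusted p = 0.0129, adjusted p = 0.520 with an estimated correlation). The count was 2311 without wild type LPS day 1 replicate 1, 723 without Rag-1 null LPS day 1 replicate 1 and 731 without Rag-1 null control replicate 1. The compared arrays alone gave 506 and array weights 2497.

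For day 4, limma called 0 probes, with 1483 at an unadjusted p under 0.05. The deposited value table gave 1205, arrays that were only centred 779, array weights 451, cyclic loess 5, 1 probe per gene 4 and slide as a block 1 or, as a random block, 4. Leaving out Rag-1 null LPS day 4 replicate 1 gave 81, wild type LPS day 4 replicate 1 gave 77, wild type LPS day 1 replicate 1 gave 38, and the other arrays gave 0 to 12. The interferon gamma list was higher as a group, with 0 of 18 past the threshold (14 higher adjusted over the list alone, list adjusted p = 8.65e-15, adjusted p = 0.181 with an estimated correlation). Its medians on the 3 slides were -0.35, 1.39 and 2.83. The alveolar type 2 list was lower, with 0 of 18 past the threshold (7 lower adjusted over the list alone, list adjusted p = 2.36e-09, adjusted p = 0.0859 with an estimated correlation).

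At day 10 the responses differed at 206 probes (105 higher, 101 lower; 215 with slide as a block), among them macrophage and endothelial genes. Saa3 differed by 3.65 ± 0.55, Clec4d by 3.04 ± 0.41, Cxcl9 by 2.89 ± 0.59, Gpnmb by 2.80 ± 0.59, Clec4e by 2.43 ± 0.50, the cholesterol hydroxylase gene Ch25h by 2.19 ± 0.35 and Ms4a6d by 2.09 ± 0.27. Cxcl9 lay above background on no wild type control array, and Clec4e on no Rag-1 null control array. The Rag-1 null change lay below that of wild type for Ednrb (-1.95 ± 0.38), Tmem100 (-1.90 ± 0.31), the endothelial transcription factor Sox18 (-1.80 ± 0.41), Bmp6 (-1.75 ± 0.31), Smad6 (-1.66 ± 0.41), Slc7a10 (-1.94 ± 0.49) and Tril (-1.81 ± 0.34). Of macrophage genes 7 of 18 were higher and 11 did not pass (9 higher adjusted over the list alone, list adjusted p = 2.86e-09, adjusted p = 4.91e-04 with an estimated correlation). Mmp12 differed by 1.63 ± 0.29, Ctsk by 1.57 ± 0.28 and Trem2 by 1.96 ± 0.42. Among endothelial genes 3 of 22 were lower and 19 did not pass (9 lower adjusted over the list alone, list adjusted p = 5.19e-09, adjusted p = 0.00601 with an estimated correlation). Cell proliferation genes were higher, with 4 of 28 higher and 24 not passing (20 higher adjusted over the list alone, list adjusted p = 2.14e-15, adjusted p = 0.178 with an estimated correlation). Mki67 differed by 1.82 ± 0.33 and Plk1 by 1.66 ± 0.34. Heart muscle genes lay lower beside them, with 1 of 8 lower and 7 not passing (4 lower adjusted over the list alone, list adjusted p = 5.31e-05, adjusted p = 0.251 with an estimated correlation). Of the calls 51.0% were higher, against 62.4% of 765 with the value table and 61.1% where arrays were only centred. Leaving out any of the 3 Rag-1 null control or 3 wild type LPS day 10 arrays, wild type control replicate 2 or Rag-1 null LPS day 10 replicate 1 or 2 gave 67 to 130. Rag-1 null LPS day 10 replicate 3 or wild type LPS day 1 replicate 1 left out gave 368 or 487, the compared arrays alone 700 and array weights 1695. Over the 3 days together 2107 probes differed by limma's F statistic (3649 without wild type LPS day 1 replicate 1).

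From day 4 to day 10, macrophage, neutrophil and cell proliferation genes fell in wild type lung and alveolar and endothelial genes rose. Saa3 fell 62.1-fold (-5.96 ± 0.39), with Cxcl9 (-4.43 ± 0.42), Arg1 (-3.78 ± 0.49), Timp1 (-3.61 ± 0.43), Retnla (-3.59 ± 0.49), Ccl3 (-3.31 ± 0.48), Clec4d (-3.16 ± 0.29) and Clec4e (-3.17 ± 0.35). Hc (3.12 ± 0.32), Pon1 (2.56 ± 0.30), Spon2 (2.45 ± 0.37), Slc7a10 (2.45 ± 0.34) and Cyp26b1 (2.76 ± 0.57) rose. Of proliferation genes 25 of 28 fell and 3 did not pass (26 fell adjusted over the list alone, list adjusted p = 1.68e-18, adjusted p = 0.106 with an estimated correlation). Mki67 changed by -1.43 ± 0.23. Macrophage genes fell, with 1 of 18 up, 14 down and 3 not passing (1 up and 15 down adjusted over the list alone, list adjusted p = 1.73e-12, adjusted p = 9.25e-05 with an estimated correlation). Neutrophil genes fell, with 12 of 17 down and 5 not passing (12 down adjusted over the list alone, list adjusted p = 1.04e-11, adjusted p = 0.106 with an estimated correlation). Alveolar type 2 genes rose, with 9 of 18 up and 9 not passing (11 up adjusted over the list alone, list adjusted p = 2.12e-06, adjusted p = 0.106 with an estimated correlation). Endothelial genes rose too, with 10 of 22 up and 12 not passing (11 up adjusted over the list alone, list adjusted p = 3.33e-05, adjusted p = 0.0607 with an estimated correlation). Heart muscle genes rose beside them, with 5 of 8 up and 3 not passing (6 up adjusted over the list alone, list adjusted p = 3.97e-04, adjusted p = 0.325 with an estimated correlation). Myl4 rose by 3.24 ± 0.86, Myl7 by 3.06 ± 0.80 and Actc1 by 3.01 ± 0.72. Above background on only some arrays of 1 group were Arg1 (1 of 3), Ccl3 (1 of 3), Clec4e (1 of 3) and Slc7a10 (2 of 3). In all 2025 probes passed (1083 higher, 942 lower; 2083 with slide as a block, 99.6% in 1 direction on every slide). Without wild type LPS day 4 replicate 1 the count was 1126, without wild type control replicate 1 and LPS day 1 replicate 1 together 3133, and with array weights 3718.

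Over the same days in Rag-1 null lung, interferon and neutrophil genes fell. Among the falls were Asprv1 (-3.76 ± 0.32), Cxcl10 (-3.53 ± 0.59), Rsad2 (-3.04 ± 0.41), the guanylate-binding protein gene Gbp5 (-3.00 ± 0.51), Isg15 (-2.99 ± 0.57) and Ifit2 (-2.97 ± 0.30). Among the rises were Hc (3.71 ± 0.32), Lrp2 (2.15 ± 0.22), the chemokine gene Ccl6 (1.99 ± 0.30), the desaturase gene Scd1 (1.91 ± 0.35) and Ccl17 (1.78 ± 0.18). Of interferon gamma genes 17 of 18 fell and 1 did not pass (18 fell adjusted over the list alone, list adjusted p = 7.45e-25, adjusted p = 0.0417 with an estimated correlation). Of type I interferon genes 13 of 18 fell and 5 did not pass (16 fell adjusted over the list alone, list adjusted p = 2.83e-18, adjusted p = 0.0417 with an estimated correlation), and of neutrophil genes 13 of 17 fell and 4 did not pass (15 fell adjusted over the list alone, list adjusted p = 3.80e-16, adjusted p = 0.0544 with an estimated correlation). Alveolar type 2 genes rose, with 14 of 18 up and 4 not passing (16 up adjusted over the list alone, list adjusted p = 1.49e-13, adjusted p = 0.0417 with an estimated correlation). The fatty acid synthase gene Fasn rose by 1.70 ± 0.27. Immediate early genes, which respond to handling, were lower, with 1 of 10 down and 9 not passing (1 down adjusted over the list alone, list adjusted p = 0.0379, adjusted p = 0.341 with an estimated correlation). In all 1308 probes passed (644 higher, 664 lower; 1328 with slide as a block, 99.4% in 1 direction on every slide). Without Rag-1 null LPS day 4 replicate 2 or 3 the count was 821 or 686, without wild type LPS day 1 replicate 1 it was 2100, and with array weights 3230.

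The change from day 4 to day 10 differed between genotypes at 83 probes, 74 of them higher in Rag-1 null lung and 9 lower (95 with slide as a block; 89.2% higher, or 74.6% where arrays were only centred). Retnla (3.13 ± 0.70), Saa3 (3.08 ± 0.55), Trem2 (2.03 ± 0.42), Ccl9 (2.02 ± 0.24) and Clec4d (1.96 ± 0.41) lay higher. Saa3 was at the highest normalized value on 2 of 3 Rag-1 null LPS day 4 arrays, which limits the fall measured there and can enlarge this difference. So did the cell division genes Prc1 (2.77 ± 0.53), Uhrf1 (2.16 ± 0.36) and Cdc20 (2.10 ± 0.39). Ednrb (-1.85 ± 0.38), Crispld2 (-1.78 ± 0.40) and Gata2 (-1.29 ± 0.26) were lower. Of proliferation genes 18 of 28 were higher and 10 did not pass (26 higher adjusted over the list alone, list adjusted p = 4.39e-48, adjusted p = 0.00764 with an estimated correlation). Mki67 differed by 1.85 ± 0.33 and Bub1b by 1.43 ± 0.21. Of macrophage genes 4 of 18 were higher and 14 did not pass (11 higher adjusted over the list alone, list adjusted p = 9.22e-15, adjusted p = 2.69e-05 with an estimated correlation). Ctsk differed by 1.91 ± 0.28 and Mmp12 by 1.80 ± 0.29. Of alternative activation genes 2 of 13 were higher and 11 did not pass (5 higher adjusted over the list alone, list adjusted p = 3.03e-07, adjusted p = 0.00764 with an estimated correlation). Ccl17 differed by 1.52 ± 0.26. Leaving out any of the 3 wild type LPS day 10 arrays, Rag-1 null LPS day 10 replicate 1 or 2, wild type LPS day 4 replicate 2 or Rag-1 null LPS day 4 replicate 2 or 3 gave 25 to 51. Without Rag-1 null LPS day 10 replicate 3 or wild type LPS day 1 replicate 1 it was 199 or 170, and array weights gave 835 and the compared arrays alone 37.

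Over the 17 comparisons, 226 list shifts were called, of which 35 held with an estimated correlation and 155 were also called by fry. The p of fry tests whether a list's genes move, on balance, 1 way and does not compare them with other genes. Of the 226, 189 had the same sign of the list median on all 3 slides, 36 on 2 slides and 1, cytokines and chemokines in the difference of the day 10 and day 4 changes, on 1 slide. The adipose list, with 3 measured genes, was called in no comparison. Its adjusted p at day 10 between genotypes was 0.0703.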

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

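The tests of background, of quantile normalization, of left-out arrays and of a clock shift that follows the inflammation were chosen only after the results were seen. The results given first passed the test of the difference between genotypes. How their counts stood against chance splits of the samples is said after.

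At day 1, where 1112 probes differed in the LPS response, Rag-1 null minus wild type was 2.75 for Clec1a, 2.50 for Saa1, 2.45 for Fcer2a, 2.29 for Ly6d, 2.24 for Akr1c14, 2.18 for Clec4n, 1.77 for Sox17 and 1.51 for Adgre1. It was -4.38 for Hamp, -3.79 for Dio2, -3.48 for Rsad2, -3.34 for Mx2, -3.22 for Il24, -3.14 for Gsta2, -2.60 for Ifit2 and -1.91 for Isg20. These are fitted values: Fcer2a and Ly6d lay above background on no Rag-1 null control array, Dio2 and Mx2 on no wild type one and Saa1 and Il24 on neither. Day 10 had 206 such probes, with Saa3 at 3.65, Clec4d at 3.04, Cxcl9 at 2.89, Gpnmb at 2.80, Clec4e at 2.43, Ch25h at 2.19, Trem2 at 1.96, Mki67 at 1.82, Ccl9 at 1.69, Plk1 at 1.66, Mmp12 at 1.63 and Ctsk at 1.57. Lower were Ednrb at -1.95, Slc7a10 at -1.94, Tmem100 at -1.90, Tril at -1.81, Sox18 at -1.80 and Bmp6 at -1.75; the macrophage list had a median of 1.04 and the endothelial list -0.57. The change from day 4 to day 10 differed at 83 probes, among them Retnla at 3.13, Saa3 at 3.08 (its Rag-1 null level at day 4 is limited by the highest normalized value), Prc1 at 2.77, Uhrf1 at 2.16, Cdc20 at 2.10, Trem2 at 2.03, Ccl9 at 2.02, Clec4d at 1.96, Ctsk at 1.91, Mki67 at 1.85, Mmp12 at 1.80, Ccl17 at 1.52, Bub1b at 1.43, Gata2 at -1.29, Crispld2 at -1.78 and Ednrb at -1.85. Its list medians were 1.34 for proliferation, 1.17 for macrophages and 0.92 for alternative activation. Over any day 2107 probes differed.

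Chance was excluded for the mean of 4 times (1691 probes, at most 580 in other splits, 1 of 100 as large, the real one included) and the F statistic (2107, at most 1617, 1 of 100). For the day 10 response difference (206, at most 183, 1 of 100) the margin was small (67 to 487 without 1 array). Chance was not excluded for the day 1 response difference (1112, up to 1733, 7 of 100), that from day 4 to day 10 (83, up to 398, 8 of 100) or at day 4 (0, up to 224, 100 of 100). With 3 arrays against 3 the 10 splits are too few; real counts and highest others were 5316 and 1163, 3152 and 1, and 278 and 1 in wild type lung at days 1, 4 and 10, and 2287, 3686 and 1202 against 0 in Rag-1 null lung. Between genotypes they were 174 and 22 in control, 3297 and 65 at day 1, 73 and 464 at day 4, where 2 of 10 splits called as many, and 748 and 0 at day 10; from day 4 to day 10 they were 2025 and 1, and 1308 and 6. The 464 point to a structure of the day 4 samples other than genotype.

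At day 4 the LPS response difference hung on the processing, with 0 probes called here and 1205 with the value table. Background that differed between arrays is argued against, since correcting it and only centring called 779. Low counts went with normalization beyond centring: 0 by quantiles with no background correction, 5 by cyclic loess. Quantile normalization stays open as the source. The log2 values had an SD of 1.18 to 1.24 in wild type control arrays and 1.33 to 1.47 in the others, and quantile normalization makes these spreads equal. Whether that narrower spread is biological or technical stays open.

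Type I interferon genes were lower in Rag-1 null than in wild type lung at day 1, 13 of 18 of them past the threshold, and higher as a list at day 4 (median 0.71, 1 of 18 past it), but with an estimated correlation neither list call held (adjusted p = 0.341 and 0.0916). Replicate 1 of wild type LPS day 1, which correlated with replicate 2 at 0.858, is argued against as the source, since 14 were lower without it. Heart and airway tissue in the 2 wild type arrays left out is argued against likewise, with 14 lower without both, although only 1 of them belongs to this comparison. Genotype stays open as an explanation, untested, as do position on the slide and the time at which each lung was taken.

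Clock genes differed between wild type lung at day 10 and control, and the time of day of sampling may be the source. Of 10 measured clock genes, the 5 not yet seen had a median change, signed by phase, of 0.351 on the log2 scale, between the values set for and against it, with 4 of 5 in the predicted direction and 0 past the threshold (Rag-1 null lung at day 10 had 0.311, with 3 of 5 and 1). A clock shift in step with the inflammation stays open as well: the median over all 10 was larger at day 10 than at day 4 by 0.844 (0.964 and 0.267 in Rag-1 null lung), but 5 of the genes were chosen for their day 10 change, which favours that outcome. Of those 5, 3 lay further from control at day 10 than at day 4. The same choice favours this, so it cannot weigh against that shift. Of the other 5, 4 moved against that shift and 1 passed (median difference 0.319, and 0.396 over all 10). Asking for 3 to pass was set after seeing the result. Nr1d1 and Tef had fallen at day 4 already (-1.50, adjusted p = 4.89e-04, and -1.18, adjusted p = 0.0229).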

How the results depend on the processing

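Leaving out the 2 wild type arrays and background correction with centring only were chosen after seeing the data. Of 781 called values of named genes, 713 to 781 stayed past the threshold in the same direction under each alternative other than the stricter filter (749 of 758), and 0 reversed; leaving out 1 array gave 717 to 779. Of 226 called list shifts, 155 stayed with fry, 35 with an estimated correlation and 201 to 226 under the others; leaving out 1 array gave 211 to 226. Reversed were cytokines and chemokines in the difference from day 4 to day 10, with medians of -0.14 without Rag-1 null LPS day 4 replicate 1 and -0.18 without wild type LPS day 4 replicate 1 (up to 0.44 without 1 other array), and skeletal muscle in the day 4 response difference, 0.065 with the value table. Except where said, the cause was not tested.

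Counts that moved by over 1.5 times are given by setting. Only the compared arrays, with the spread taken from them alone, gave 2117 in wild type lung at day 1. Rag-1 null lung had 4319 and 1983 at days 1 and 10. Between genotypes they gave 93, 803, 15 and 1526 in control and at days 1, 4 and 10. The response differences were 506 and 700 at days 1 and 10, and 37 from day 4 to day 10. The value table gave 5166 and 1337 in wild type lung at days 4 and 10, 940 between genotypes in control, response differences of 1205 and 765 at days 4 and 10, and 3518 by the F statistic. Centring only gave 4737 and 497 in wild type lung at days 4 and 10, 187 between genotypes at day 4, a day 4 response difference of 779 and 126 for day 4 to day 10. The stricter filter gave 132 in wild type lung at day 10 and 84 between genotypes in control, 1 probe per gene gave 101 there and 4 in the day 4 response difference, and cyclic loess gave 5 in the latter. Array weights gave 986 in wild type lung at day 10, 4906, 5920 and 3417 in Rag-1 null lung, 486, 994 and 3261 between genotypes in control and at days 4 and 10, 3781 for the mean of 4 times, response differences of 2497, 451 and 1695, 3718 and 3230 from day 4 to day 10, 835 for their difference and 5204 by the F statistic. Without the 2 wild type arrays the counts were 575 in wild type and 1854 in Rag-1 null lung at day 10, 335, 193 and 1253 between genotypes in control and at days 4 and 10, 2930 for the mean, 2148, 100 and 567 for the response differences, 3133 and 2251 from day 4 to day 10, 194 for their difference and 3868 by the F statistic.

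Leaving out 1 array gave 4695 to 6142, 1869 to 4291 and 62 to 663 in wild type lung, and 1468 to 3268, 2721 to 4663 and 783 to 1752 in Rag-1 null lung at days 1, 4 and 10. Between genotypes it gave 58 to 350 in control, 2346 to 4417, 14 to 311 and 403 to 1156 at the 3 days and 1240 to 2921 for the mean. Response differences were 723 to 2311, 0 to 81 and 67 to 487, the changes from day 4 to day 10 1126 to 2951 and 686 to 2100, their difference 25 to 199, the F statistic 1507 to 3649 and called lists 213 to 235. The highest count came without wild type LPS day 1 replicate 1, the array with the lowest weight (0.0990), except between genotypes at day 4 and the day 4 response difference (Rag-1 null LPS day 4 replicate 1), the difference from day 4 to day 10 (Rag-1 null LPS day 10 replicate 3) and the lists (wild type control replicate 1).

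The replicate numbers did not pair the samples: deviations from the group mean correlated at 0.0477 on average between arrays of 1 number (84 pairs, -0.493 to 0.372, 38.1% over 0.1) and at -0.0235 between numbers. With the number, and so the slide, as a block the day 4 response difference was 1, and no other count moved by over 1.5 times; as a random block, with a correlation of 0.0155, it was 4. The block ended 2 list calls, airway in Rag-1 null lung from day 4 to day 10 and alveolar type 1 in wild type lung at day 4, and the calls of Adgre1, C1qb, Cd274, Emp2, Hpgd, Ifit2, Klrk1 and Tnf in 1 comparison each. Signal over background limits genes above it on no array of a group, which have only a bound; 11.9% of simulated log2 changes of 0.5 were recovered in the day 10 response difference.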

Other observations

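Heart muscle genes varied between arrays of 1 group. Over the 8 measured genes the mean log2 intensity was 7.76, 5.83 and 5.15 in the 3 wild type control arrays, 7.58, 5.36 and 5.92 at day 1, 4.83, 4.91 and 6.42 at day 4 and 7.48, 7.83 and 6.96 at day 10. In Rag-1 null lung it was 7.71, 6.27 and 7.72 in control, 5.47, 5.32 and 5.81 at day 1, 6.52, 5.27 and 4.95 at day 4 and 6.32, 7.04 and 5.80 at day 10. The airway epithelial list averaged 9.13, 7.96 and 7.66 in wild type control, 8.10, 6.89 and 7.09 at day 1, 7.18, 7.28 and 8.13 at day 4 and 8.75, 8.70 and 8.45 at day 10. In Rag-1 null lung that list averaged 8.90, 7.88 and 8.84 in control, 7.14, 6.98 and 7.30 at day 1, 7.94, 7.31 and 7.07 at day 4 and 7.53, 8.18 and 7.80 at day 10.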
